A study of Mus musculus with 12 samples.

How the data were processed

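RNA was measured by mRNA sequencing in 12 libraries of primary mouse megakaryocytes, the cells that release platelets, from C57BL/6J animals. The libraries covered 4 genotypes with 3 libraries each: wildtype, Lyl1 knockout, Scl (gene symbol Tal1) knockout, and the double knockout of both genes. Per the labels' protocols, the cells were grown in a serum-containing medium with recombinant thrombopoietin, RNA was taken with a column kit, and libraries were made with a TruSeq mRNA kit.

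One table of whole-number read counts per Ensembl gene was deposited for all 12 libraries. Per the submitters' processing notes, STAR 2.5.2b, featureCounts, Subread 1.5.2 and the genome build GRCm38 were used to make it. The notes do not state the annotation release, the strand setting or the rule by which the genes of the deposited count table were chosen. Reads from overlapping genes on opposite strands, and reads shared by near-identical genes such as Hba-a1 and Hba-a2, were therefore treated as uncertain in origin. The deposited counts held 13727 genes, of which 13717 were matched to GENCODE M21 by identifier for symbols and GRCm38 coordinates, and 13644 were protein-coding. Total counts per library ran from 23555079 to 28515922. All columns of values in the table were used.

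Genes were tested in R 4.3.3 with the quasi-likelihood F test of edgeR 4.0.16, with robust estimation of the spread, TMM scaling and the tool's own filter on low counts, which left 12897 genes. All 12 libraries were in 1 fit with a term for genotype. The 6 comparisons were the double knockout with wildtype, each single knockout with wildtype, the double knockout with each single knockout, and the interaction. The interaction is the double-minus-Scl difference less the Lyl1-minus-wildtype difference on the log2 scale. Adjusted p-values are Benjamini-Hochberg values over all tested genes of 1 comparison with a threshold of 0.05, from edgeR unless another tool is named. Standard errors of log2 fold changes (SE) were derived from the fold change and the F statistic. Counts scaled to a common library total (CPM) were computed from the deposited counts, with each library's total multiplied by its TMM factor. They are given as mean ± SD over the 3 libraries of a genotype.

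The comparisons, the tests, 26 gene lists and the rule for naming genes were fixed before the data were examined. Lists were tested with camera in limma 3.58.1 at a preset correlation between genes of 0.01, adjusted over the 24 lists tested. The sex-linked transcripts were kept as a check without a test, and the hepatocyte markers had fewer than 5 tested members. Beside each list call lost with an estimated correlation, that p is given. Fry, a test of whether the genes of 1 list move in 1 direction on balance, was run as an alternative.

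The rule named Tal1 and Lyl1 in all genotypes. It then took, for the double knockout and wildtype, the 10 largest rises and 10 largest falls past the threshold with an average log2 CPM of at least 2 and no overlap between the groups' libraries, and 5 of each for the other comparisons. The no-overlap condition was not applicable to the interaction. Predicted genes and pseudogenes were left out. Up to 4 members with the smallest p were named from each list described for the double knockout and wildtype, and up to 2 for the other comparisons, with 10 transcription factors in the first. Values of those 10 factors in the other comparisons, and any gene said to have been chosen after its values were seen, fall outside the rule.

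For a group with no reads of a gene, the lower bound of a fold change used a floor of 3 counts over the group. For groups with few reads, ratios of summed counts were given with exact 95% Clopper-Pearson intervals. Floors and intervals cover counting error only. The test steps were tested on simulated counts with 200 changed genes at known folds.

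The alternatives were relative log expression scaling, library totals without scaling, no filter beyond 1 read, a minimum of 5 CPM in 3 libraries, DESeq2 1.42.0, limma voom, a fit of 2 genotypes only, the replicate number of the titles as a block, a term for the S number in the labels (1 to 6 or 7 to 12), a fit without robust estimation, and each library left out in turn. A term for libraries with Y-linked transcripts, fits within each range of the S number, and counts without genes within 20 Mb of Lyl1 were added after seeing the data. The replicate numbers were checked by the correlation of deviations from the genotype means. Between the Scl and double knockouts every pair with 1 number was over 0.1 (0.45, 0.21 and 0.15), so the numbers may pair these libraries. However, libraries 2 and 3 of these genotypes, in 1 range of the S number, correlated as highly across numbers (0.17 and 0.25). The correlations can thus follow the S number range, and a pairing by number is not established. Between the other genotypes the numbers were not taken to pair libraries. Other groupings of the same libraries were refitted: 10 for each pair of genotypes, and 100 for the interaction and the joint count. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.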

Results

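Transcript levels were measured by mRNA sequencing in 12 megakaryocyte cultures of 4 genotypes, with 3 libraries each: wildtype, Lyl1 knockout, Scl knockout and double knockout. Scl, whose gene symbol is Tal1, and Lyl1 are related basic helix-loop-helix transcription factors of blood cells, and the study asked what they share in platelet production. Total counts per library were 25718432, 25058801 and 27983093 in wildtype, 25062370, 28515922 and 28489293 in the Lyl1 knockout, 25816780, 26576921 and 28381942 in the Scl knockout, and 23884982, 25383077 and 23555079 in the double knockout. The labels do not say whether the 3 libraries of a genotype came from separate animals, so each p-value measures the spread between these cultures. The labels carry an S number from 1 to 12 with no stated meaning. All wildtype libraries and replicate 1 of each knockout had 7 to 12, and replicates 2 and 3 of each knockout had 1 to 6, so fits with a term for these ranges and fits within them were also made, and some list and gene calls changed in them. The first principal component of the libraries held 48.8% of the variance and the second 13.9%.

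The targeted genes were examined first. Tal1 (ENSMUSG00000028717, GRCm38 chromosome 4, 115056426 to 115071755) was at 569, 663 and 525 CPM in wildtype and at 592, 639 and 549 CPM in the Lyl1 knockout. It was at 97.2, 120 and 120 CPM in the Scl knockout and at 80.9, 103 and 103 CPM in the double knockout. Tal1 fell in the Scl knockout, with a log2 change of -2.38 (SE 0.14, adjusted p = 2.68e-06), and in the double knockout, with -2.62 (SE 0.14, adjusted p = 2.99e-07). Lyl1 (ENSMUSG00000034041, chromosome 8, 84701457 to 84704715) was at 206, 198 and 152 CPM in wildtype, 180 ± 49.6 CPM (SD, n = 3, from 123 to 215) in the Scl knockout, 88, 93.2 and 88.5 CPM in the Lyl1 knockout, and 58.8, 90.3 and 110 CPM in the double knockout. In the double knockout Lyl1 fell by 1.10 (SE 0.24, adjusted p = 0.00346). In the Lyl1 knockout its log2 change was -1.04 (SE 0.24), all 3 libraries were below all 3 of wildtype, and the adjusted p was 0.268 with an unadjusted p of 0.000892. That value passed with DESeq2 (adjusted p = 0.00984), with a term for the S number range (0.0327) and with the 2 genotypes fitted alone, and the highest among its alternatives was 0.904. The labels do not give the deleted exons, so reads left at either gene do not measure intact transcript.

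**Figure D1:**
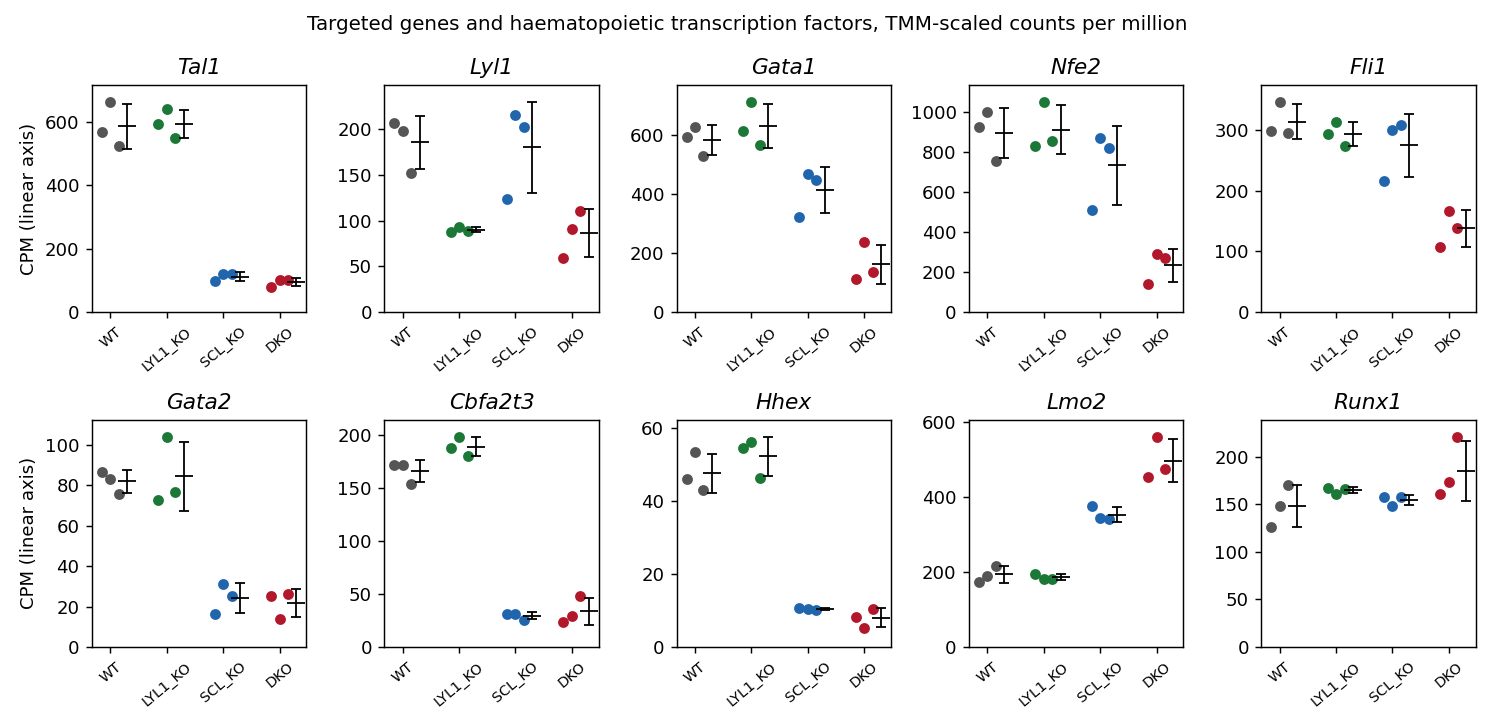
Levels of the targeted genes and of blood transcription factors in CPM, with 1 dot per library and bars for the mean ± SD of 3 libraries per genotype. Tal1 averaged 112 CPM in the Scl knockout and 95.4 CPM in the double knockout against 585 CPM in wildtype.

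The double knockout was compared with wildtype to measure the effect of losing both factors. Transcripts of platelet function were lower in it. Thbs1 (ENSMUSG00000040152, chromosome 2, 118111876 to 118127133), which encodes the alpha granule protein thrombospondin 1, fell from 20200 ± 1730 CPM to 419 ± 25 CPM (SD, n = 3 each), a log2 change of -5.59 (SE 0.24, adjusted p = 5.88e-08). P2ry12 (ENSMUSG00000036353, chromosome 3, 59216272 to 59262871), the ADP receptor that clopidogrel blocks, fell from 152 ± 45.6 CPM to 5 ± 3.11 CPM, a log2 change of -4.93 (SE 0.50, adjusted p = 1.98e-05). Of 42 platelet receptor and signalling genes, 33 fell, 1 rose (Plcg2, a phospholipase of receptor signalling) and 8 did not pass; adjusted over the list alone, 34 fell and 1 rose, and under library totals 27 fell and 2 rose. Their median log2 change was -1.26 under TMM scaling and -0.86 under scaling to library totals (camera adjusted p = 3.11e-14; adjusted p = 0.575 with an estimated correlation). Other members that fell were F2rl2, a thrombin receptor subunit (-2.34), Adra2a, the platelet adrenaline receptor (-2.89), and Itga2, a collagen receptor chain (-2.75). Where 5 or fewer members of a list moved in 1 direction, they are named here and in what follows, and such names were chosen after the values were seen.

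Alpha granule, cytoskeleton and inherited platelet disorder genes were also lower as lists in the double knockout, while dense granule genes were not (median 0.02, camera adjusted p = 0.598). Of 26 alpha granule genes, 15 fell and 4 rose, and adjusted over the list alone 18 fell and 4 rose (median -1.05, camera adjusted p = 3.64e-06; adjusted p = 0.346 with an estimated correlation). Pdgfb, a platelet growth factor, fell by 2.98, the coagulation factor gene F5 fell by 2.92, and Lgals3bp fell by 1.27. The 4 that rose were Vegfa, Serpine2, Cd63 and Nbeal2, a gene needed for granule formation. Under library totals 14 alpha granule genes fell and 7 rose (median -0.65). Selp, the gene of the granule membrane protein P-selectin, was at 0.21 (SE 0.12, adjusted p = 0.175) and was chosen after its value was seen. Of 39 cytoskeleton genes used in proplatelet formation, 28 fell and 0 rose, 30 and 0 adjusted over the list alone, but under library totals 17 fell and 6 rose (median -0.24). Among these Tuba4a, an alpha tubulin, fell by 2.88, Lims1 fell by 1.75, Was, an actin regulator, fell by 1.62, and Rac1 fell by 1.53. Tubb1, the megakaryocyte beta tubulin, fell by 4.98 (SE 0.66, adjusted p = 0.00013) and was also chosen after its value was seen. The list's median was -0.65 (camera adjusted p = 1.69e-09; adjusted p = 0.575 with an estimated correlation). Of 46 inherited platelet disorder genes, 26 fell and 3 rose (Mecom, Kdsr, Nbeal2), and adjusted over the list alone 28 fell and 4 rose (median -0.79, camera adjusted p = 5.13e-07; adjusted p = 0.575 with an estimated correlation). Under library totals 22 of these fell and 11 rose (median -0.38). Slfn14, a ribosome-associated nuclease, fell by 6.42 and Gp1bb, a chain of the von Willebrand factor receptor, fell by 1.76.

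Transcription factors of blood cells moved in both directions. The Scl partner Lmo2 rose from 193 ± 22 CPM to 496 ± 57 CPM (SD, n = 3 each), by 1.36 (SE 0.11, adjusted p = 5.29e-06). Gata1 fell from 584 ± 50.8 to 162 ± 68 CPM, a log2 change of -1.85 (SE 0.25, adjusted p = 0.000153), and Nfe2, a factor needed for platelet release, fell from 894 ± 126 to 234 ± 81.4 CPM, a log2 change of -1.93 (SE 0.27, adjusted p = 0.000211). Gata2 fell by 1.92, Fli1 fell by 1.18, the corepressor gene Cbfa2t3 fell by 2.3 and Hhex fell by 2.57. Zfpm1 was at -0.23 (SE 0.13, adjusted p = 0.204), Ldb1 at 0.00 (SE 0.12, 0.993), Runx1 at 0.32 (SE 0.13, 0.0707) and Gfi1b at -0.36 (SE 0.22, 0.23). Under library totals Ldb1 (0.41) and Runx1 (0.73) passed upward and Zfpm1 and Gfi1b changed sign. Gfi1b passed downward with a term for the S number range (-0.77, adjusted p = 0.00307) and among S numbers 7 to 12 (-1.0, 0.00672), and Runx1 passed with the replicate number as a block (0.0439). Of 24 listed factors, 10 fell and 6 rose, 10 and 7 adjusted over the list alone; the median was -0.29 and turned to 0.11 under library totals, and camera gave an adjusted p of 0.173. Under library totals 10 rose and 8 fell, and among S numbers 7 to 12 the list passed downward (0.00526), as it did with fry (0.00612).

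The largest rises in the double knockout were in genes with few or no reads in wildtype. Gzmc (ENSMUSG00000079186, chromosome 14, 56231441 to 56234656) and Gzmb (ENSMUSG00000015437, chromosome 14, 56258838 to 56262260), proteases of cytotoxic granules, had 0.0432 ± 0.0424 and 0.251 ± 0.396 CPM in wildtype (SD, n = 3 each). In the 3 double knockout libraries Gzmc reached 330, 178 and 97 CPM and Gzmb 563, 162 and 106 CPM. From the summed counts, Gzmc was 4940-fold higher (95% interval 1690 to 23900); the family's members are similar in sequence, so the split of reads between them is uncertain. Calca (ENSMUSG00000030669, chromosome 7, 114631478 to 114636357), the precursor of calcitonin and its related peptide, reached 243 ± 161 CPM and was 4470-fold higher (1750 to 16400). Igsf5 was at least 501-fold higher, Otop1, a proton channel, 637-fold (273 to 1960) and Clstn2 357-fold (153 to 1100). Npy2r, a neuropeptide Y receptor, rose by 8.66 (SE 0.65), Sp7, a factor of bone-forming cells, by 7.97 (SE 0.45), and Car8 by 7.40 (SE 0.55), with adjusted p from 3.99e-07 to 2.68e-06. The Y-linked Ddx3y was at least 1190-fold higher, through double knockout 2 and 3, which held 72.6 and 77 CPM; Lyl1 knockout 1 held 63.8 CPM and no other library more than 0.118. With limma voom the Otop1 call ended (0.0617) and so did that of Ddx3y (0.509), which also ended with the block (0.0719), the S number term (0.112) and among S numbers 7 to 12 (0.273). The Ddx3y adjusted p of 0.0406 rose to between 0.0693 and 0.099 without double knockout 2 or 3 or without any 1 wildtype library. All 4 listed Y-linked transcripts passed in this comparison (Ddx3y, Eif2s3y, Kdm5d, Uty), and Xist was not in the table. Sex may thus differ between libraries and be partly confounded with genotype, so these rises can follow sex and not the knockouts. With a term for Y-linked transcripts, 17 of 244 named gene results over all comparisons lost their call.

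The 10 largest falls named by rule in the double knockout included both alpha globin genes and the platelet disorder gene Slfn14. Hba-a1 (ENSMUSG00000069919, chromosome 11, 32283511 to 32284465), an alpha globin gene, fell from 205 ± 46.1 to 0.721 ± 0.444 CPM (SD, n = 3 each), a log2 change of -8.15 (SE 0.47, adjusted p = 4.48e-07). Its near-identical copy Hba-a2 was 122-fold lower (95% interval 61.5 to 283), and reads of the pair cannot be assigned with certainty. Plp1 (ENSMUSG00000031425, chromosome X, 136822671 to 136839733), a myelin protein gene, fell from 149 ± 28.8 to 1.07 ± 0.342 CPM, and Mest, an imprinted gene, from 299 ± 92.6 to 2.19 ± 1.67 CPM. Nefh, a neurofilament gene, fell by 6.98 (SE 0.33), Tmcc2 (ENSMUSG00000042066, chromosome 1, 132356315 to 132391281) fell by 6.65 (SE 0.19), Jhy fell by 6.48 (SE 0.41) and Acer2, a ceramidase, fell by 6.42 (SE 0.45), with adjusted p from 4.01e-09 to 1.63e-06. Olfr552, an olfactory receptor gene, fell by 6.91 (SE 1.63, adjusted p = 0.00596). With a term for Y-linked transcripts its adjusted p was 0.0646, the highest of a range from 0.000239. It was low in the Lyl1 knockout too, at 0.207 ± 0.0752 CPM against 16.7 ± 1.38 CPM in wildtype.

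**Figure D2:**
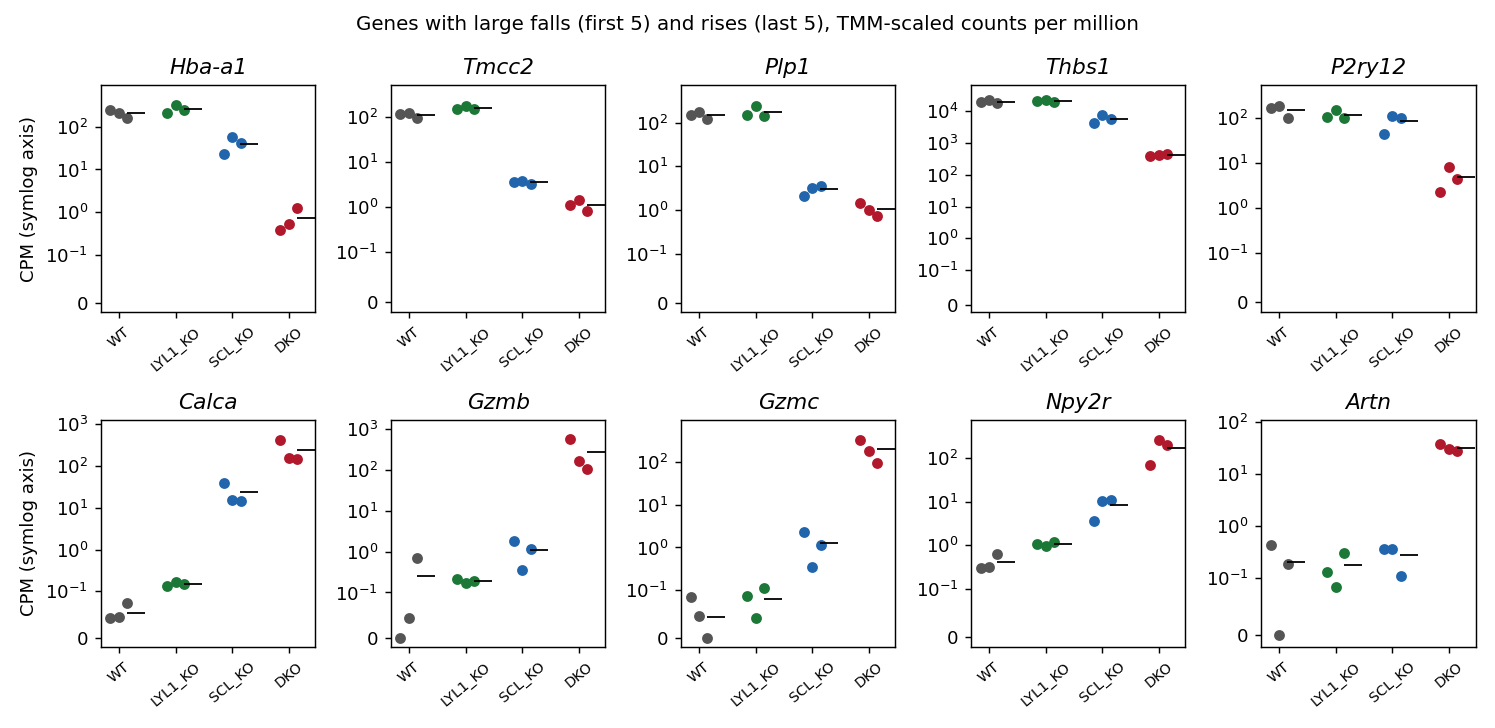
Levels of selected genes with large rises and falls in the double knockout against wildtype, not in every case the largest. Values are in CPM on an axis that is linear near 0 and logarithmic above, with 1 dot per library and a bar at each genotype's mean. Gzmc averaged 0.0432 CPM in wildtype and was at 330, 178 and 97 CPM in the double knockout, and Hba-a1 averaged 205 and 0.721 CPM.

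Erythroid, progenitor and interferon genes were also lower as lists in the double knockout under TMM, and for the progenitor genes the calls were balanced under library totals. Of 20 tested erythroid markers, 10 fell and 1 rose (the embryonic globin gene Hbb-bh1), 11 and 1 adjusted over the list alone (median -1.49, camera adjusted p = 4.45e-13, and adjusted p = 0.0137 with an estimated correlation). Under library totals 10 fell and 3 rose (median -1.07). Spta1, erythroid spectrin, fell by 4.31 (SE 0.22) and the glycophorin gene Gypa fell by 3.89 (SE 0.23). Of 24 stem and progenitor genes, 10 fell and 3 rose (Cd34, Mecom, Ly6a), the same numbers adjusted over the list alone (median -0.48, camera adjusted p = 0.0296; adjusted p = 0.346 with an estimated correlation). Under library totals 7 fell and 7 rose (median -0.08). Sox4 fell by 3.75 (SE 0.30), the surface receptor gene Slamf1 fell by 4.06 (SE 0.44) and Mllt3 fell by 1.49 (SE 0.13). Of 23 interferon response genes, 13 fell and 1 rose (Ifih1), 15 and 1 adjusted over the list alone (median -1.10, camera adjusted p = 0.00289; adjusted p = 0.853 with an estimated correlation). Under library totals 6 fell and 2 rose (median -0.68), and among S numbers 7 to 12 the list call ended (0.0502). Ifit2 fell by 2.23, Ifit1 fell by 2.72, Isg15 fell by 2.23 and Stat1 fell by 0.62; the Ifit genes are close copies. The Stat1 call ended under library totals (adjusted p = 0.2) and among S numbers 7 to 12 (0.0533), over a range of its alternatives from 0.000272 to 0.2.

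Under TMM and edgeR with all libraries, tested marker lists of other cell types did not pass in the double knockout, but some did in alternatives. Macrophage markers passed downward under library totals (0.0182) and with limma voom (0.02), and stromal markers under library totals (0.0036) and with the 2 genotypes alone (0.00337). Neutrophil markers had a median of 0.38 over 20 genes with 1 up (Ms4a3, adjusted p = 0.0469) and 1 down (Mpo, 0.0428; camera adjusted p = 0.445), and both calls ended without single libraries. Under library totals 6 rose and 0 fell (median 0.80). Without 1 of double knockout 2 or 3, or wildtype 2 or 3, Ms4a3 had 0.0526 to 0.195, and without any 1 double knockout library, wildtype 1 or wildtype 2, Mpo had 0.0828 to 0.158; Mmp8 (0.63, adjusted p = 0.108) and S100a8 (0.82, 0.128) did not pass, but did under library totals (0.00673 and 0.0149). The Ms4a3 and Mpo calls also ended with limma voom (0.0611 and 0.0542) and among S numbers 7 to 12 (0.523 and 0.151), Ms4a3 with the block (0.0743) and the S number term (0.15) and Mpo under library totals (0.246). Macrophage markers had a median of -0.86 over 23 genes with 8 down and 0 up, 5 and 0 adjusted over the list alone, and 2 and 0 under library totals (median -0.44, camera adjusted p = 0.0841 under TMM). Mrc1 (-1.37), Csf1r (-0.92), Cd163 (-3.29) and Mafb (-1.0) fell with adjusted p from 0.0143 to 0.0282. Each of these 4 calls ended without wildtype 1 (0.0744 for Mrc1, 0.099 for Csf1r, 0.0961 for Cd163, 0.153 for Mafb). Mrc1 also ended without double knockout 2 (0.0506), Csf1r without double knockout 2 or 3 (0.0699 and 0.0605), Cd163 without double knockout 1 or 3 or wildtype 2 (0.0706 to 0.0918), and Mafb without any 1 double knockout library (0.056 to 0.0762). Mast cell and basophil markers had a median of -1.06 over 14 genes with 3 down (Cpa3, Mcpt8, Gata2; camera adjusted p = 0.361; 1 up and 1 down under library totals), and eosinophil markers -0.47 over 9 genes with 0 past the test (0.774; Gata2 and Ccr3 stand on more than 1 list). Dendritic cell genes had -0.50 over 17 genes with 5 down (Flt3, Siglech, Zbtb46, Ccr7, Bst2; 0.243), but 2 up and 2 down under library totals (median -0.08). Lymphoid markers had 2 up, Gzmb and the surface antigen gene Thy1 (4.55, SE 0.73, adjusted p = 0.000516), and 3 down, the B cell genes Ebf1 (-3.76), Pax5 (-3.29) and Cd19 (camera adjusted p = 0.581, median -0.85 over 11 genes). Stromal and endothelial markers had a median of -1.91 over 18 genes, with 8 down, among them Lyve1 (-3.09) and Tagln (-3.18), and 2 up, Stab2 (3.41) and the chemokine gene Cxcl12 (3.16; camera adjusted p = 0.105, and 0.0244 among S numbers 7 to 12); under library totals 6 were down and 2 up. Of 4 tested hepatocyte markers Apoa2 rose and Afp fell. Among S numbers 7 to 12, with 1 double knockout library, the calls of Mrc1, Csf1r, Cd163 and Mafb ended too. Their log2 changes there were -1.33, -0.68, -4.24 and -1.04. The calls of Pax5, Stab2 and Tagln also ended among these S numbers, with log2 changes of -3.73, 3.4 and -2.67.

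**Figure D3:**
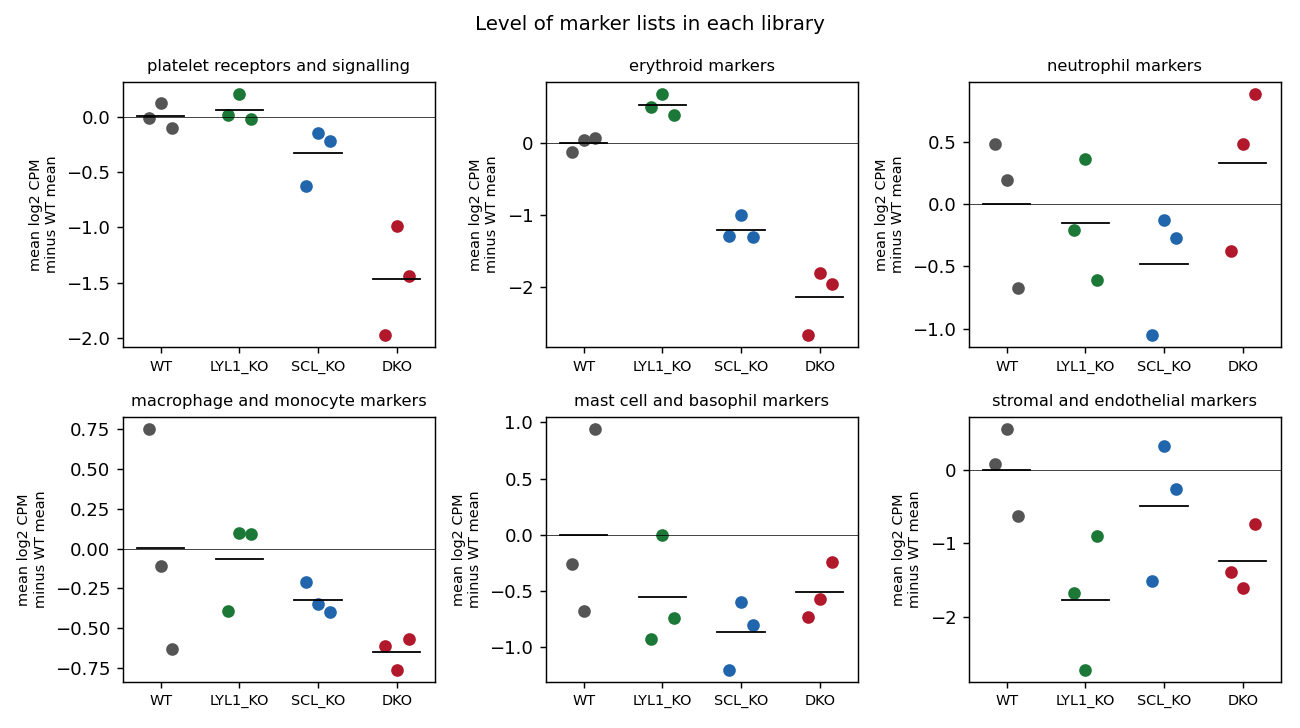
Mean log2 CPM of the tested members of 6 gene lists in each library, less the wildtype mean, with 1 dot per library. Platelet receptor genes stood at -1.97, -0.99 and -1.44 in the 3 double knockout libraries and between -0.63 and 0.20 in all other libraries.

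In total 4883 of 12897 genes changed between the double knockout and wildtype, 2357 up and 2526 down, and 2088 of them by at least 2-fold (812 up, 1276 down). Scaled to library totals, 7338 changed and 81.3% of these were higher against 48.3% under TMM, with a median over all genes of 0.45 against 0.04. The TMM factor was 1.23 ± 0.07 in the double knockout and 0.922 ± 0.036 in wildtype (SD, n = 3 each), and the 10 most abundant genes took 6.31% ± 0.95 and 10.3% ± 0.41 of the counts. Among S numbers 7 to 12, with 1 double knockout library, 2398 genes changed and 11 lists passed, 3 of them upward, against 7 lists and 0 upward with all libraries. With a term for the S number range 10 lists passed, 3 of them upward. The 3 upward lists were DNA replication, mitosis and mitochondrial transcripts in both. In simulated counts for this comparison, 87.9% of genes set to change 4-fold, 53.7% at 2-fold and 20.9% at 1.5-fold were called. Far fewer genes were set to change there than passed in the real comparison, so a smaller unadjusted p was needed to pass. These shares therefore do not measure how many small changes were missed here, and some may have been.

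The Scl knockout was compared with wildtype to measure the loss of Scl alone. Erythroid and progenitor genes were lower in it as lists, while most of their members did not pass. Tmcc2 fell from 114 ± 16.2 to 3.57 ± 0.258 CPM (SD, n = 3 each), a log2 change of -5.0 (SE 0.17, adjusted p = 3.12e-08), and Spta1 fell by 3.86 (SE 0.22, adjusted p = 1.78e-06). Plp1 fell by 5.66 (SE 0.30), the sarcosine dehydrogenase gene Sardh fell by 4.24 (SE 0.35), Prrt4 fell by 4.24 (SE 0.70) and Tmem132b fell by 4.01 (SE 0.44). Calca rose from 0.0539 ± 0.0179 to 23.3 ± 14.4 CPM and was 428-fold higher (95% interval 167 to 1570), and Clstn2 was 46-fold higher (19.5 to 143). Slc5a5, the iodide transporter gene, rose by 4.53 (SE 0.33) and Npy2r by 4.26 (SE 0.64, adjusted p = 0.00226). Gzmc was 31.4-fold higher (10.4 to 155), with an adjusted p of 0.0334 that rose to between 0.0677 and 0.122 without Scl knockout 1 or 3 or any 1 wildtype library. With limma voom the calls of Calca (0.0842), Npy2r (0.182) and Gzmc (0.408) ended, over ranges from 3.97e-18, 8.39e-14 and 0.000418.

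Erythroid markers had 7 of 20 down and 0 up in the Scl knockout, 9 and 1 adjusted over the list alone (median -0.61, camera adjusted p = 2.82e-19, and adjusted p = 0.00543 with an estimated correlation). Stem and progenitor genes had 4 down (Sox4 at -1.96, Gata2 at -1.75, Mllt3, Pbx1) and 1 up (Cd34), 6 and 1 adjusted over the list alone (median -0.54, camera adjusted p = 0.000274, and adjusted p = 0.0241 with an estimated correlation). Of the 24 transcription factors 5 fell (Cbfa2t3 at -2.5, Hhex at -2.2, Gata2, Ets1, Pbx1) and Lmo2 rose by 0.87 (SE 0.11, adjusted p = 0.000883), with a camera adjusted p of 0.00756 and an adjusted p = 0.565 with an estimated correlation. Gata1 (-0.49, SE 0.24, adjusted p = 0.299), Nfe2 (-0.29, 0.611), Fli1 (-0.19, 0.595), Zfpm1 (0.08, 0.802), Ldb1 (0.21, 0.357), Runx1 (0.06, 0.867) and Gfi1b (-0.05, 0.935) did not pass, but Nfe2 did with a term for the S number range (-0.75, 0.0356). In the interferon list, Stat1 fell by 0.61 and Ifit2 was at -0.85 (adjusted p = 0.053, and 0.0112 to 0.0487 with the block, the S number term, library totals and DESeq2); 1 of 23 passed, and 10 adjusted over the list alone (camera adjusted p = 2.67e-05; adjusted p = 0.583 with an estimated correlation). The Stat1 call (0.0241) ended without Scl knockout 1 or 2 or wildtype 1 or 2 (0.0672 to 0.0965), with the 2 genotypes alone (0.0683) and among S numbers 7 to 12 (0.18).

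Platelet genes moved less often in the Scl knockout than the erythroid list, a difference between lists that was not tested. Of 42 receptor and signalling genes 1 fell (Adra2a at -3.78, SE 0.26, adjusted p = 1.02e-05), with Plcg2 at 0.38 (0.0717, but 0.0388 under library totals and 0.00908 with DESeq2), a median of -0.28, a camera adjusted p of 0.00296 and an adjusted p = 0.924 with an estimated correlation. Of 26 alpha granule genes 4 fell (Thbs1 at -1.77 with 5930 ± 1600 CPM, Pdgfb at -2.06, Pdgfa, Lgals3bp) and 2 rose (Timp3, Serpine2), 5 and 3 adjusted over the list alone (camera adjusted p = 0.014; adjusted p = 0.714 with an estimated correlation). Both list calls ended without Scl knockout 1 (0.183 and 0.117). Inherited platelet disorder genes had Slfn14 down and Kdsr up of 46 (camera adjusted p = 0.171), and of 39 cytoskeleton genes only Tubb2a passed, downward (0.213). The medians of those lists, -0.10 and -0.05, were 0.00 and 0.05 under library totals, but with a term for the S number range both lists passed downward (0.000589 and 0.00119). Mast cell markers (camera adjusted p = 0.00234), eosinophil markers (0.00972), neutrophil markers (0.0187) and macrophage markers (0.035) were lower as lists, with 0.565, 0.714, 0.924 and 0.924 as adjusted p with an estimated correlation. The mast cell call ended without wildtype 3 (0.0673), the eosinophil call without Scl knockout 1 (0.117) or wildtype 1 (0.0991), the neutrophil call without Scl knockout 1 (0.223) or wildtype 1 (0.212), and the macrophage call without Scl knockout 2 (0.0742) or 3 (0.0811), while without wildtype 1 its direction turned (0.62). Among their members Hdc, a histamine enzyme gene, fell by 1.71 (adjusted p = 0.0326) and Prg2, an eosinophil granule gene, fell by 1.17 (0.0444), whereas Epx (-1.92, 0.0608), Mpo (-0.75, 0.15), Ctsg (-0.94, 0.211), Ccr2 (-0.82, 0.174) and Itgam (-0.51, 0.195) did not pass. Ctsg did with the S number term (-1.46, 0.0278) and Epx with DESeq2 (0.0101). With the S number term the macrophage call ended (0.0562), as it did with the block (0.0641), and dendritic (0.0343) and stromal lists (0.0459) passed downward. The Hdc call ended without any 1 Scl knockout library or wildtype 2 or 3 (0.0529 to 0.116), and the Prg2 call without any 1 Scl knockout library or wildtype 1 or 3 (0.06 to 0.176). Both ended with limma voom (0.0589 and 0.0872), with the 2 genotypes alone (0.0724 and 0.0539) and among S numbers 7 to 12 (0.197 and 0.194), and Prg2 with the block (0.0537).

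Between the Scl knockout and wildtype 815 genes changed, 380 up and 435 down, 362 of them by at least 2-fold. Under library totals 1031 changed, 63.3% of them higher against 46.6% under TMM, with a median over all genes of 0.12. The count was 398 to 514 without wildtype 1 or 2 or any 1 Scl knockout library, and 301 among S numbers 7 to 12, with 1 Scl knockout library.

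The Lyl1 knockout was compared with wildtype to measure the loss of Lyl1 alone. All 10 genes that changed with edgeR lie on chromosome 8, as Lyl1 does. Prdx2 (ENSMUSG00000005161, 84969587 to 84974834), a peroxiredoxin gene, rose from 67.3 ± 1.72 to 162 ± 3.84 CPM (SD, n = 3 each), by 1.27 (SE 0.08, adjusted p = 4.51e-05). Adgrl1 (ENSMUSG00000013033, 83900105 to 83941954), an adhesion receptor gene, fell from 65.6 ± 11.3 to 10.8 ± 2.17 CPM, a log2 change of -2.61 (SE 0.22, adjusted p = 0.000433). Phkb rose by 1.37 (SE 0.14), Fbxo31 by 0.91 (SE 0.13), Gipc1 by 0.78 (SE 0.10) and Cacna1a, a calcium channel gene, by 4.0 (SE 0.56), while Adgre5 fell by 1.54 (SE 0.14), Rnf150 fell by 1.11 (SE 0.14), Mri1 fell by 0.89 (SE 0.10) and Mast1 fell by 5.95 (SE 0.83). Mast1 and Cacna1a were outside the naming rule and chosen after their values were seen. Of these genes 9 lie within 5 Mb of Lyl1, and Fbxo31 is 36.9 Mb away. Among the 85 tested genes within 5 Mb, 42.4% had an unadjusted p under 0.05 against 7.95% of the others (Fisher's exact test, 2-sided, p = 1.02e-17). Olfr552, chosen after its values were seen, was not among the 10 genes. It nevertheless averaged 16.7 ± 1.38 CPM in wildtype and 0.207 ± 0.0752 CPM in the Lyl1 knockout. The Scl knockout libraries in the same fit spread widely for it (0.619, 0.0395 and 22.5 CPM).

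**Figure D4:**
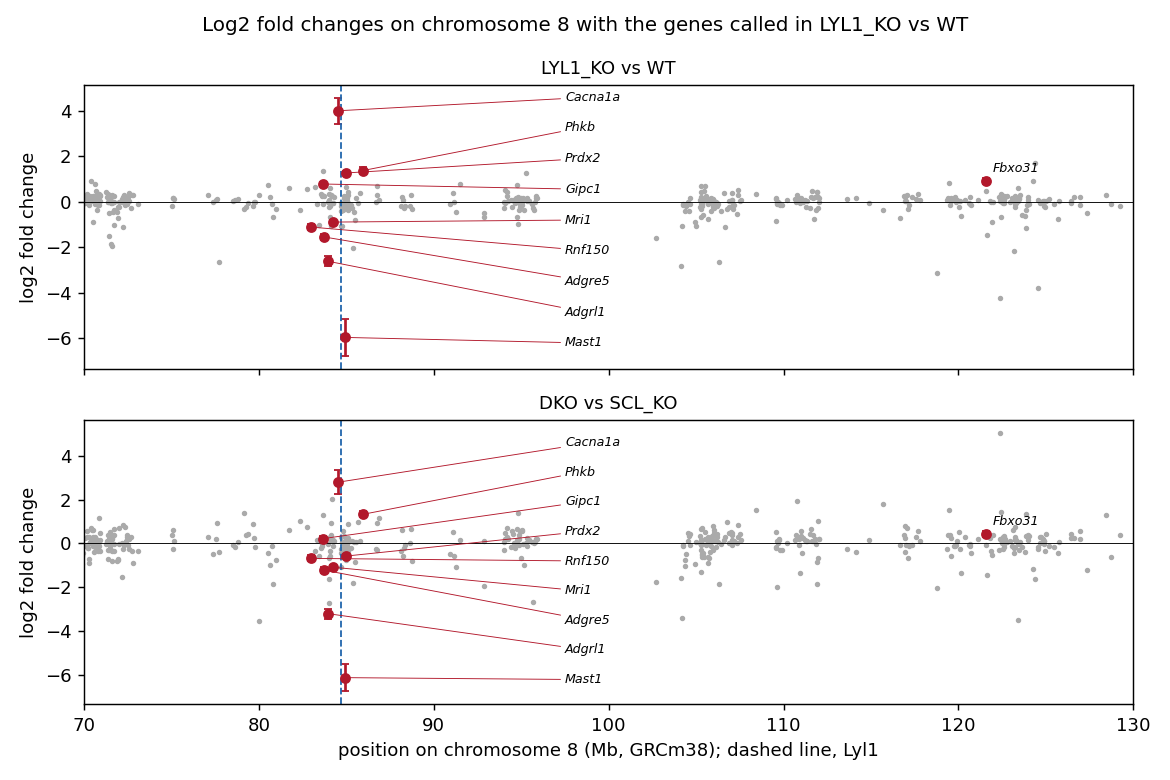
Log2 fold changes with standard errors, against position on chromosome 8, of the genes that changed between the Lyl1 knockout and wildtype, shown for that comparison and for the double knockout against the Scl knockout. Prdx2 stands at 1.27 in the first and at -0.57 in the second.

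No member of the platelet lists and none of the named blood factors passed in the Lyl1 knockout with edgeR. Of the receptor list 0 of 42 genes changed (median 0.09, camera adjusted p = 0.122, direction up), but with a term for the S number range the receptor list passed downward (0.00452), as did inherited platelet disorder genes (0.019). With the 2 genotypes alone the receptor list passed upward (0.0343). Gata1 was at 0.11 (SE 0.24, adjusted p = 0.942), Nfe2 at 0.03 (0.988), Fli1 at -0.10 (0.921), Gata2 at 0.04 (0.985), Lmo2 at -0.05 (0.942), Cbfa2t3 at 0.19 (0.853), Zfpm1 at 0.19 (0.737), Ldb1 at -0.09 (0.895), Runx1 at 0.15 (0.805) and Gfi1b at 0.06 (0.976). Erythroid markers were higher as a list (median 0.43, camera adjusted p = 1.28e-05; adjusted p = 0.222 with an estimated correlation) with 0 of 20 past the test over all genes and 4 up adjusted over the list alone; Gypa was at 0.72 (adjusted p = 0.409) and Tmcc2 at 0.49 (0.425). The p53 targets were also higher as a list (median 0.23, camera adjusted p = 1.28e-05; adjusted p = 0.607 with an estimated correlation), with Bbc3 at 0.42 (0.409) and Trp53inp1 at 0.60 (0.478). Stromal and endothelial markers were lower (median -1.74, camera adjusted p = 3.69e-12; adjusted p = 0.222 with an estimated correlation), with 0 past over all genes and 7 down adjusted over the list alone; Pdgfra was at -3.0 (0.322) and Pdgfrb at -2.52 (0.409); Pdgfra (0.00939), Pdgfrb (0.0176) and Gypa (0.0143) passed with DESeq2. With the S number term neutrophil (0.00357) and eosinophil lists (0.00531) passed downward. Lymphoid markers (camera adjusted p = 0.000645), cholesterol synthesis genes (0.00081), mast cell markers (0.00578) and dendritic cell genes (0.0472) were lower as lists, with 0.457, 0.607, 0.582 and 0.607 as adjusted p with an estimated correlation. Members with the smallest p were Ebf1 (-1.62, adjusted p = 0.478), Cd79a (-2.09, 0.523), Hmgcs1 (-0.58, 0.354), Sc5d (-0.30, 0.493), Ccr3 (-2.15, 0.506), Il1rl1 (-1.61, 0.624), Siglech (-1.78, 0.541) and Ccr7 (-1.13, 0.587). The mast cell call ended without Lyl1 knockout 1 (0.0647) or wildtype 3 (0.778), and the dendritic cell call without Lyl1 knockout 1 (0.173) or 3 (0.0631) or wildtype 1 (0.63).

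The Lyl1 knockout count was 10 with edgeR (1056 at an unadjusted p under 0.05), 96 with DESeq2, 9 with a replicate block, 24 with the 2 genotypes alone and 16 with a term for the S number range; under library totals it was 9. It was 40 without wildtype 3, and 4 to 6 without wildtype 1 or 2 or Lyl1 knockout 2 or 3. Among S numbers 7 to 12, with 1 Lyl1 knockout library, the calls of the 8 genes named by rule ended. Their log2 changes there were similar to those with all libraries: Phkb 1.36, Prdx2 1.28, Fbxo31 0.89, Gipc1 0.78, Adgrl1 -2.4, Adgre5 -1.78, Rnf150 -0.94 and Mri1 -0.9. The calls of Fbxo31 (0.102 to 0.245) and Gipc1 (0.0541 to 0.102) ended without wildtype 1 or 2 or any 1 Lyl1 knockout library, that of Rnf150 without wildtype 2 or Lyl1 knockout 2 or 3 (0.0586 to 0.0726), and that of Mri1 without Lyl1 knockout 2 (0.0516). The Fbxo31 call also ended with the S number term (0.0586), under library totals (0.152) and with limma voom (0.0534). In simulated counts for this comparison 89.4% of genes set to change 4-fold and 64.2% at 2-fold were called by edgeR. Among genes left unchanged there, edgeR called 9 and DESeq2 34, so part of the further DESeq2 calls may be false.

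The double knockout was compared with the Scl knockout to measure what the loss of Lyl1 added when Scl was already lost. Platelet and erythroid lists were lower, though only 6 of 20 erythroid markers passed and with an estimated correlation the list calls ended (adjusted p = 0.429 for 4 platelet lists and 0.339 for erythroid markers). Thbs1 fell by 3.82 (SE 0.22, adjusted p = 3.97e-06), P2ry12 fell by 4.10 (SE 0.48, adjusted p = 0.000191), Slfn14 fell by 4.65 (SE 0.53) and F2rl2 fell by 1.78 (SE 0.19). Hba-a1 fell from 40.3 ± 17 to 0.721 ± 0.444 CPM (SD, n = 3 each), a log2 change of -5.80 (SE 0.44, adjusted p = 1.22e-05), and Sptb, a spectrin gene, from 405 ± 76.9 to 61.8 ± 13.1 CPM, a log2 change of -2.71 (SE 0.18). Rgs8, a regulator of G-protein signalling, fell by 5.29, Acer2 fell by 5.23, Nefh fell by 4.96 and Col1a1, a collagen gene, fell by 4.86. Gzmb rose by 7.97 (SE 0.81), Otop1 by 8.26 (SE 0.94), Gzmc by 7.29 (SE 0.58) and Artn (ENSMUSG00000028539, chromosome 4, 117926162 to 117929763), a neurotrophic factor gene, by 6.81 (SE 0.55). Uty, a Y-linked gene, was at least 808-fold higher through double knockout 2 and 3, which can follow sex and not the loss of Lyl1. The Uty call (adjusted p = 0.0499) ended without double knockout 2 or 3 or any 1 Scl knockout library (0.0752 to 0.127), and that of Col1a1 (0.021) without any 1 double knockout library or Scl knockout 2 (0.0602 to 0.108). With limma voom the Otop1 call ended (0.0742, over a range from 1.24e-10), and with the replicate number as a block those of Uty (0.0904) and Col1a1 (0.0523) did, as with the S number term (0.0765 and 0.0563).

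As lists, 31 of 42 platelet receptor genes fell and 1 rose (Adra2a) between the Scl and the double knockout, 34 and 2 adjusted over the list alone (median -0.94, camera adjusted p = 2.68e-16). Of 39 cytoskeleton genes 25 fell and 0 rose, 28 and 0 adjusted over the list alone (1.43e-13), with Was at -1.33 and Tuba4a at -2.01. Of 46 inherited platelet disorder genes 23 fell and 1 rose (Mecom; 2.04e-09), 28 and 3 adjusted over the list alone. Of 26 alpha granule genes 12 fell and 1 rose (Vegfa by 1.52, SE 0.17; 1.83e-06), 15 and 2 adjusted over the list alone. Those 4 calls had an adjusted p = 0.429 with an estimated correlation. Under library totals 25 receptor genes fell and 2 rose, 19 and 2 of the cytoskeleton, 21 and 7 of the inherited disorders, and 12 and 5 of the alpha granules. Erythroid markers had 6 of 20 down and 0 up, 6 and 1 adjusted over the list alone, and 6 and 2 under library totals (camera adjusted p = 7.11e-05; adjusted p = 0.339 with an estimated correlation). Neutrophil markers were higher as a list (median 0.90, camera adjusted p = 0.00366; adjusted p = 0.97 with an estimated correlation) with 3 of 20 up over all genes (S100a8 by 1.36, Mmp8 by 1.06, S100a9) and 0 adjusted over the list alone; under library totals 13 rose and 0 fell (median 1.22). The neutrophil list call ended without double knockout 3 (0.0689) or Scl knockout 1 (0.0784). S100a8 (0.0344) ended without double knockout 2 or 3 or any 1 Scl knockout library (0.0602 to 0.148), and Mmp8 (0.0238) without double knockout 3 or any 1 Scl knockout library (0.0592 to 0.11). S100a8 also ended with limma voom (0.0505) and among S numbers 1 to 6 (0.0843), and with a term for Y-linked transcripts the list (0.155), S100a8 (0.325) and Mmp8 (0.225) did.

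Lyl1 itself was lower in the double than in the Scl knockout, at -1.06 (SE 0.24, adjusted p = 0.00803), with 0.0543 when the 2 genotypes were fitted alone, over a range of alternatives from 0.000228. Tal1 was at -0.24 (SE 0.13, adjusted p = 0.243). Of the transcription factors, Gata1 fell by 1.36 (SE 0.25, adjusted p = 0.00251), Nfe2 fell by 1.65 (SE 0.27, 0.00145) and Fli1 fell by 0.99 (SE 0.17, 0.00183) between the Scl and the double knockout, and Lmo2 rose by 0.49 (SE 0.11, 0.00865). Cbfa2t3 (0.20, 0.522), Gata2 (-0.16, 0.699), Zfpm1 (-0.31, 0.128), Ldb1 (-0.21, 0.227), Runx1 (0.26, 0.174) and Gfi1b (-0.31, 0.363) did not pass, and under library totals Runx1 did (0.57). In all 2800 genes changed, 1234 up and 1566 down, 1076 of them by at least 2-fold. Under library totals 4670 changed, 80.8% of them higher against 44.1% under TMM, with a median over all genes of 0.33. The count was 1553 without Scl knockout 2 and 1666 without Scl knockout 3.

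The double knockout was compared with the Lyl1 knockout to measure what the loss of Scl added when Lyl1 was already lost. Platelet receptor, cytoskeleton, inherited platelet disorder, alpha granule, erythroid and interferon genes were lower as lists, but with an estimated correlation only the erythroid call was kept (0.00693, the others 0.49 to 0.949). Stem and progenitor genes did not pass (camera adjusted p = 0.143, median -0.33), but passed downward in camera under library totals (0.0347, although the median was 0.13) and at a minimum of 5 CPM (0.0444). Thbs1 fell from 21100 ± 1590 to 419 ± 25 CPM (SD, n = 3 each), a log2 change of -5.65 (SE 0.24, adjusted p = 5.25e-08), Tmcc2 fell by 7.14 (SE 0.19), Spta1 fell by 4.89 (SE 0.23) and Hba-a1 fell by 8.46 (SE 0.47). Plp1, Nefh and Mest fell by 7.37, 7.41 and 7.35, and Hba-a2 was 233-fold lower (95% interval 118 to 542). Gzmc was 2480-fold higher (1140 to 6750), Car8 422-fold (204 to 1050) and Igsf5 at least 503-fold, while Gzmb rose by 10.46 (SE 0.97) and Calca by 10.61 (SE 0.75). Of 42 platelet receptor genes 35 fell and 1 rose (Plcg2), the same numbers adjusted over the list alone (median -1.38, camera adjusted p = 6.12e-16), with Adra2a at -3.25 and F2rl2 at -2.54. Of 39 cytoskeleton genes 30 fell and 0 rose (camera adjusted p = 1.04e-10), with Tuba4a at -3.03 and Was at -1.59, and of 46 inherited platelet disorder genes 27 fell and 3 rose (Nbeal2, Mecom, Kdsr; 3.09e-07), with Slfn14 at -5.98 and Gp1bb at -2.11. Those 3 calls had an adjusted p = 0.506 with an estimated correlation. Of 26 alpha granule genes 14 fell, with Pdgfb at -3.06, and 4 rose (Timp3, Serpine2, Nbeal2, Vegfa; camera adjusted p = 2.49e-06, adjusted p = 0.49 with an estimated correlation). Adjusted over the list alone, 30 cytoskeleton, 28 inherited disorder and 16 alpha granule genes fell. Under library totals 29 receptor genes fell and 2 rose, 21 and 5 of the cytoskeleton, 23 and 11 of the inherited disorders, and 12 and 7 of the alpha granules.

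Erythroid markers had 12 of 20 down and 1 up (Hbb-bh1) between the Lyl1 and the double knockout, 14 and 1 adjusted over the list alone and 11 and 2 under library totals (median -2.09, camera adjusted p = 2.31e-16, and adjusted p = 0.00693 with an estimated correlation). Interferon genes had 9 of 23 down and 1 up (Ifih1), also adjusted over the list alone, and 5 down and 4 up under library totals (camera adjusted p = 0.0408; adjusted p = 0.949 with an estimated correlation), with Ifit1 at -3.28 and Ifit2 at -2.07; the list call ended without double knockout 2 (0.175) or Lyl1 knockout 1 (0.123), with the block (0.0517), the S number term (0.0772), at a minimum of 5 CPM (0.109) and among S numbers 1 to 6 (0.0776). Tal1 fell by 2.64 (SE 0.14, adjusted p = 2.64e-07) and Lyl1 was at -0.06 (SE 0.23, 0.875). Gata1 (-1.96), Nfe2 (-1.96), Gata2 (-1.96), Cbfa2t3 (-2.49) and Fli1 (-1.08) fell and Lmo2 rose (1.41). Zfpm1 fell by 0.42 (adjusted p = 0.0275), but its direction turned under library totals (0.04), and the call ended without double knockout 1 or 3 or any 1 Lyl1 knockout library (0.0544 to 0.0845). Ldb1 (0.09, adjusted p = 0.587), Runx1 (0.17, 0.332) and Gfi1b (-0.41, 0.169) did not pass; Ldb1 (0.54) and Runx1 (0.63) did under library totals and Gfi1b with the S number term (-0.47, 0.0164). In all 4991 genes changed, 2503 up and 2488 down, 2017 of them by at least 2-fold; under library totals 7566 changed, 84.1% of them higher against 50.2%, with a median over all genes of 0.53.

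The interaction measured whether the loss of both genes departed from the sum of the single losses. Negative values were found in platelet and erythroid genes: Thbs1 was at -3.88 (SE 0.28, adjusted p = 7.72e-05), Gp1bb at -2.01 (SE 0.28, 0.00166), F2rl2 at -1.98 (SE 0.27, 0.00149), Hba-a1 at -6.12 (SE 0.54, 0.000137) and Sptb at -2.81 (SE 0.24, 0.000136). Nefh (-5.39), Rgs8 (-5.25), Acer2 (-5.18), Hba-a2 (-4.94), Slfn14 (-4.20), Tuba4a (-2.17) and Was (-1.29) were negative too. Positive values were found in Gzmb (8.46), Thy1 (7.63), Artn (7.02), Car8 (6.46), the splicing factor gene Rbfox2 (5.26) and Vegfa (1.54). Of the factors, Nfe2 (-1.68), Gata1 (-1.47), Fli1 (-0.89) and Lmo2 (0.55) passed, and Tal1 (-0.25, adjusted p = 0.439), Lyl1 (-0.01, 0.986), Cbfa2t3 (0.01, 0.991), Gata2 (-0.21, 0.775), Zfpm1 (-0.50, 0.116), Ldb1 (-0.13, 0.688), Runx1 (0.11, 0.754) and Gfi1b (-0.36, 0.515) did not. Several of these calls ended without single libraries: Lmo2 (0.0466) without double knockout 2 or 3, any 1 Lyl1 knockout library, Scl knockout 2 or 3, or wildtype 2 or 3 (0.0665 to 0.121), and Fli1 (0.0348) without double knockout 3, any 1 Lyl1 knockout library, Scl knockout 2 or 3, or wildtype 1 or 3 (0.055 to 0.0914). Gata1 (0.0201) ended without double knockout 3, Lyl1 knockout 2, or Scl knockout 2 or 3 (0.051 to 0.0592), and Gzmb (0.0263) without Lyl1 knockout 2 (0.0559) or wildtype 3 (0.715). With the replicate number as a block Lmo2 ended (0.0568), with the S number term Lmo2 (0.0703) and Fli1 (0.0514), with limma voom Gzmb (0.274) and Lmo2 (0.0514), and under library totals Fli1 (0.056). Among S numbers 7 to 12, with 1 library of each knockout, Gzmb, Artn, Car8, Acer2, Slfn14, Vegfa, Was, Nfe2, Fli1 and Lmo2 did not pass (0.0517 to 0.876).

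By lists, 17 of 42 platelet receptor genes had a negative interaction and 0 a positive one, 27 and 0 adjusted over the list alone (median -1.0, camera adjusted p = 1.24e-16). The numbers were 18 and 0 of 39 for the cytoskeleton (1.13e-13), 17 and 1 (Mecom) of 46 for inherited platelet disorders (5.41e-09), and 8 and 1 (Vegfa) of 26 for alpha granules (2.17e-06), or 28 and 0, 22 and 1, and 12 and 1 adjusted over the list alone. Those 4 calls had an adjusted p = 0.45 with an estimated correlation. Under library totals the negative and positive counts were 15 and 0 for receptors, 14 and 1 for the cytoskeleton, 13 and 4 for inherited disorders, and 8 and 3 for alpha granules. Erythroid markers had 8 negative and 0 positive of 20, 10 and 1 adjusted over the list alone, and 5 and 1 under library totals (camera adjusted p = 5.39e-09; adjusted p = 0.0584 with an estimated correlation). Neutrophil markers were positive as a list with 0 of 20 past the test, but 5 positive under library totals (median 1.01, camera adjusted p = 0.00329; adjusted p = 0.944 with an estimated correlation), with Mmp8 at 1.35 (0.0577) and Cxcr2 at 2.65 (0.0596), both of which passed under library totals, with DESeq2 and with the S number term (0.00798 to 0.041), and the list call ended without Scl knockout 1 (0.0663). In all 1414 genes passed, 538 positive and 876 negative, 809 of them beyond 2-fold; under library totals 2575 passed, 80.2% of them positive against 38%, with a median over all genes of 0.40. The count was 719 to 888 without Lyl1 knockout 2, Scl knockout 2 or 3, or double knockout 3, and 159 among S numbers 7 to 12. In simulated counts, 77.3% of interactions of 4-fold and 35.8% of 2-fold were called.

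**Figure D5:**
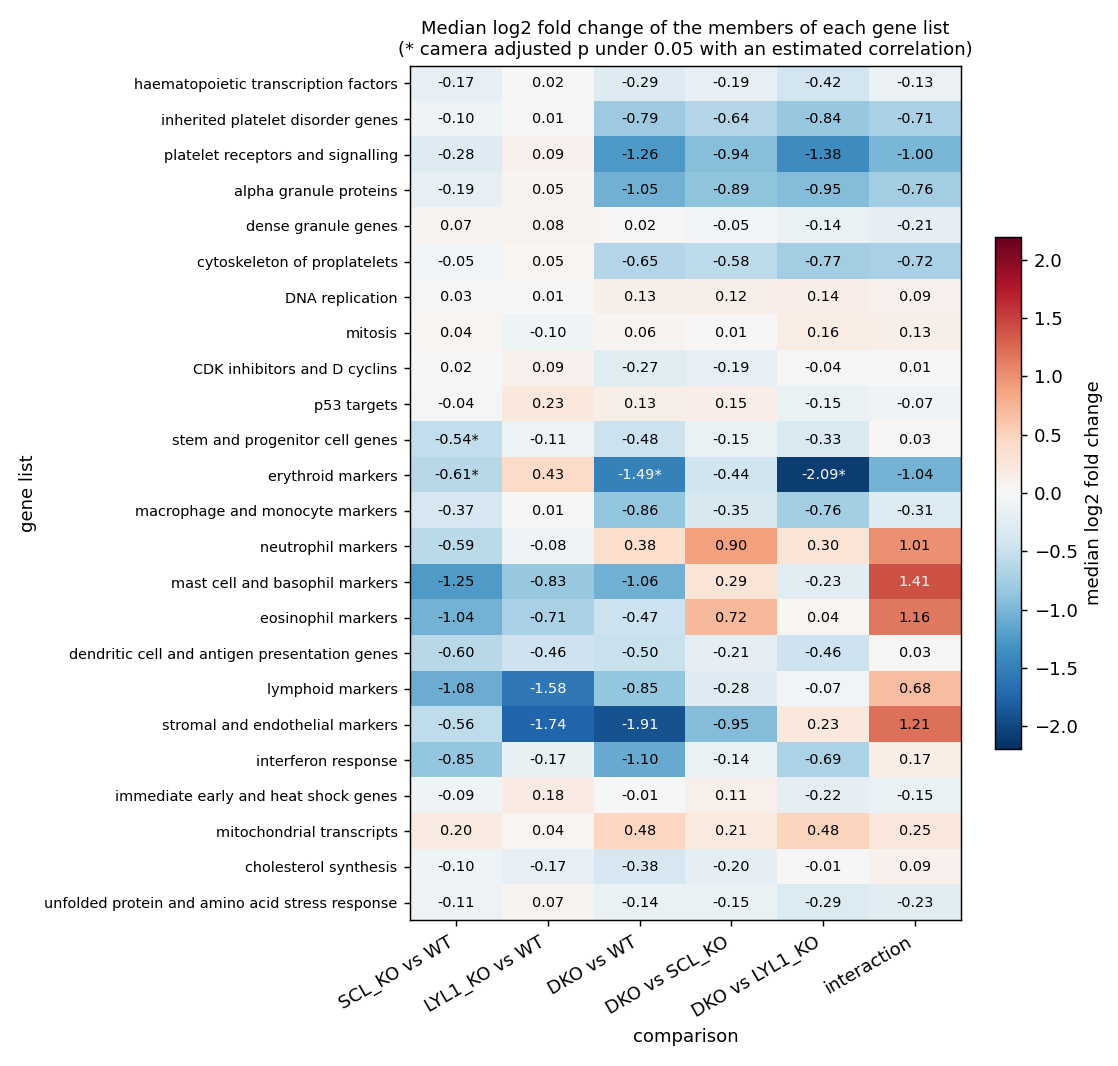
Median log2 fold change of each gene list in each comparison, where a star marks an adjusted p under 0.05 with an estimated correlation between genes. The erythroid list carries stars for the double knockout and the Scl knockout against wildtype and for the double against the Lyl1 knockout, and the stem and progenitor list carries 1 for the Scl knockout against wildtype.

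A joint count asked which genes separated the double knockout from all other genotypes. In it, 2277 genes differed in 1 direction from wildtype and from both single knockouts, 972 higher and 1305 lower, and 1212 of these also passed the interaction test. The 3 tests share the double knockout libraries. The joint count was 4098 under library totals, 1377 without Scl knockout 2 and 1457 without Scl knockout 3. Of the genes that changed in the Scl knockout, 316 were higher and 404 lower in both the Scl and the double knockout against wildtype and 10 went opposite ways, where independent calls would give 69.4 and 85.2. Both comparisons use the same wildtype libraries. In each of 20 simulated data sets with no change in any genotype, 0 genes were called in both, but these leave out the real effects, so part of the excess over independent calls may come from the shared libraries.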

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

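The tests of explanations below were all chosen only after the results they address were seen, while the interaction test and the counts over other splits of the libraries were planned.

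These results stand out because the effect of losing both genes differed from the sum of the single effects, by the interaction test itself. It called 1414 genes and 6 gene lists, and 0 lists with an estimated correlation. Hba-a1 (-6.12), Nefh (-5.39), Rgs8 (-5.25), Acer2 (-5.18) and Hba-a2 (-4.94) had the most negative log2 values of the named genes that passed it, and Gzmb (8.46), Thy1 (7.63), Artn (7.02), Car8 (6.46) and Rbfox2 (5.26) the most positive. The blood factors with a difference were Nfe2 (-1.68), Gata1 (-1.47), Fli1 (-0.89) and Lmo2 (0.55), but Lmo2 ended with the replicate number as a block (adjusted p = 0.0568) and Lmo2 (0.0703) and Fli1 (0.0514) with a term for the S number range. Gzmb ended with limma voom (0.274). In 100 regroupings of the 12 libraries, 2 gave at least 1414 genes, the real one included, and the highest other regrouping gave 2317. That regrouping kept the 3 double knockout libraries together in 1 group, so it follows in part the real structure of the samples. For the 6 lists chance is not excluded, since 95 of 100 regroupings gave as many and the highest other gave 21. For the joint count of 2277 genes the highest other was 1, and for the 3 of 4 target gene tests past the threshold it was 0. The target gene tests follow from the labels, which name the genes knocked out. Regrouped sets mixed genotypes, which widens the spread within a set, and their fits left out any pairing of the Scl and double knockout libraries. They are thus no null for any of these counts and do not exclude chance.

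For pairs of genotypes there are 10 splits, too few for a share under 0.05. The real and highest other gene counts were 4883 and 0 for the double knockout and wildtype, 815 and 1 for the Scl knockout, 10 and 1 for the Lyl1 knockout, 2800 and 2 for the double and the Scl knockout, and 4991 and 4 for the double and the Lyl1 knockout. For lists they were 7 and 15, 10 and 18, 7 and 13, 6 and 12, and 6 and 13 in the same order. As many lists as in the real split came from 10, 6, 10, 9 and 9 of the 10 splits, and as many genes from 1 in each comparison. The number of lists called at the preset correlation was thus often as high in other splits. Each other split mixed the 2 genotypes and is no null, so this count does not decide whether the list calls follow the genotypes.

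Genes called in the Lyl1 knockout lay around Lyl1 on chromosome 8. A difference between the S number ranges is argued against as the whole cause: with a term for it, 42.4% of genes within 5 Mb still had an unadjusted p under 0.05 against 14.7% of the others (Fisher's exact test, 2-sided, p = 8.86e-10). DNA linked to the targeted allele, by strain variants beside it or by the targeted change, stays open. Of the 9 called genes in the window, 7 differed in the same direction between the double and the Scl knockout. Those genotypes also differ in the loss of Lyl1 itself, so this count does not separate linked DNA from loss of the protein. Prdx2 went the other way there (-0.57), and Gipc1 did not pass (adjusted p = 0.14). By the place of the genes around Lyl1, the changes may come from the allele's surroundings and not from loss of the protein, which was not tested further.

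Platelet receptor and signalling genes fell in the double knockout. Scaling is argued against as the whole cause, since under library totals the median was -0.86 with 0.45 for all genes. So are the S number ranges, with a median of -1.58 under a term for them. Among S numbers 7 to 12 the median was -1.80, but it rests on double knockout 1, the lowest library of its genotype for this list (mean -1.97). A lower share of megakaryocytes alone would raise markers of every other cell type alike. The mean level of neutrophil less erythroid markers was 2.28, 2.28 and 2.84 in the double knockout and 0.60, 0.14 and -0.74 in the wildtype libraries, on a log2 scale relative to wildtype, so the means lay 2.47 apart (SD 0.32 and 0.68, n = 3 each). This measure replaced a permutation of single genes after its result was seen, because genes of a list correlate, and what was expected was reworded to match. Erythroid markers were also lower as a list in the Scl knockout, so their fall may come from the loss of Scl. The gap between the 2 lists can then open at any share of megakaryocytes, so it does not decide on that share. A change in the share of cells, or more neutrophils, stays open. A loss of expression in megakaryocytes without both factors, direct or through Gata1 and Nfe2, is a candidate explanation. Which of these routes applies, and whether maturation was arrested, was not tested.

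Gzmb, Gzmc and Thy1 rose in the double knockout. Lymphoid or natural killer cells would bring their other abundant transcripts, but the largest rise among those listed was 0.19 CPM, for Nkg7, against 277 CPM for Gzmb. Only 4 of the 8 transcripts chosen were in the table, and because Il7r was already at 44.5 CPM in wildtype and at 29.9 CPM in the double knockout, the rise was read in place of the level first written down. The mast cell and basophil genes Cpa3, Ms4a2, Fcer1a and Hdc had a median of -1.06, so they did not rise over wildtype with Gzmb. The wildtype libraries differed widely in such genes. The mean log2 level of the mast cell list was -0.26, -0.68 and 0.94 in wildtype and -0.73, -0.57 and -0.24 in the double knockout. Between the Scl and the double knockout its median was 0.29. More mast cells or basophils than in wildtype are thus argued against, but a rise over the Scl knockout is not decided. Expression of these genes in the double knockout cells themselves is a candidate explanation; the 3 libraries held 563, 162 and 106 CPM of Gzmb.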

How the results depend on the processing

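The fits within S number ranges, with a term for Y-linked transcripts and without genes near Lyl1 were chosen only after the data were seen, as was the rule that a gene's sign change counts as reversed only if it passed in either fit. Of 4534 values of 244 gene results under alternatives, 4271 kept direction and side of the threshold, 217 lost the call, 45 gained one and 1 reversed; 74 further sign changes, in 27 results, never passed. Of 2844 values of 144 list results, 2612 kept both, 92 lost the call, 132 gained one and 8 reversed. DESeq2 gave no adjusted p for 2 named results. The causes of the changes below were not tested.

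Under library totals the gene counts were 7338 for the double knockout and wildtype, 4670 and 7566 for the double against the Scl and Lyl1 knockouts, 2575 for the interaction and 4098 jointly. DESeq2 called 1276 genes in the Scl knockout, 96 in the Lyl1 knockout and 2162 in the interaction. In the simulated counts DESeq2 called 30, 34 and 26 unchanged genes in these comparisons, where edgeR called 2, 9 and 2. Calls gained only with DESeq2 are thus less certain. With 2 genotypes fitted alone the Lyl1 knockout had 24 and the double against the Scl knockout 1644. A minimum of 5 CPM in 3 libraries left 4 lists in the Lyl1 knockout.

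With a term for the S number range the double knockout had 10 lists against wildtype, 3 of them upward, the Lyl1 knockout had 16 genes and 15 lists, the Scl knockout 16 lists and the interaction 13. Among S numbers 7 to 12, with 1 library of each knockout assumed to vary like the wildtype, the double knockout had 2398 genes and 11 lists, the Scl knockout 301 and 16, the Lyl1 knockout 6 and 12, and the interaction 159 and 11. Among S numbers 1 to 6 the double knockout differed from the Scl knockout in 3439 genes and from the Lyl1 knockout in 5504. Without genes within 20 Mb of Lyl1, 1 gene was left in the Lyl1 knockout.

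With an estimated correlation 1 list passed for the double knockout and wildtype, 2 for the Scl knockout, 0 for the Lyl1 knockout, 0 and 1 for the double against the Scl and Lyl1 knockouts, and 0 for the interaction. Fry called 8 lists for the double knockout and wildtype, 3 for the Scl knockout and 0 for the Lyl1 knockout. It called 5 and 9 for the double against the Scl and Lyl1 knockouts, and 5 for the interaction.

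Leaving out each library in turn gave 3649 to 5129 genes and 7 to 9 lists for the double knockout and wildtype, 398 to 964 and 6 to 12 for the Scl knockout, and 4 to 40 and 8 to 12 for the Lyl1 knockout. It gave 1553 to 3009 and 5 to 7 for the double against the Scl knockout, 3608 to 4734 and 5 to 7 against the Lyl1 knockout, 719 to 1840 and 5 to 10 for the interaction, 1377 to 2399 jointly, and 3 of the target gene tests each time. The libraries behind changes over 1.5 times are named with the comparisons above. For lists, these were wildtype 2 or 3 or Lyl1 knockout 2 in the Lyl1 knockout (12 each), Scl knockout 1 in the Scl knockout (6), and Lyl1 knockout 2 or Scl knockout 2 in the interaction (10 each).

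Reversed results were Zfpm1 between the double and the Lyl1 knockout under library totals (0.04), and lists given here by adjusted p. In the Lyl1 knockout these were mitosis (2.29e-06), platelet receptors (0.00452) and inherited platelet disorder genes (0.019) with the S number term, macrophage markers without wildtype 3 (0.0103), and mitosis (0.000901) and macrophage markers (0.0203) among S numbers 7 to 12. The others were mitosis in the interaction with the S number term (0.0256) and macrophage markers in the Scl knockout without wildtype 1 (0.62). Over all libraries left out in turn, the macrophage adjusted p ran from 7.51e-05 to 0.62 in the Scl knockout, and in the Lyl1 knockout from 4.3e-08 (without wildtype 1) to 0.734.

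With the replicate number as a block the counts were 4851, 889, 9, 2889, 5065 and 1614 genes for the double, Scl and Lyl1 knockouts against wildtype, the double against the Scl and the Lyl1 knockout, and the interaction, and 2355 jointly. Over all genotypes 6 of 18 pairs with 1 number had a correlation over 0.1 (median -0.01, other pairs 0.02), and 5 of 12 libraries correlated best with their own number. Between the Scl and double knockouts the block ended the calls of Uty (0.0904) and Col1a1 (0.0523) and no other named or list call. Simulated 1.5-fold changes were often missed, and depth was not varied. They were called in 17.9% to 29.9% of genes in pairs of genotypes and in 4.48% for the interaction. The number of genes set to change was the same in each simulation, while the real counts of called genes differed widely. These shares therefore do not measure how many small changes were missed in each real comparison.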

Other observations

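No test of an explanation was run for the values in this part, and the genes named in it from list counts were chosen after their values were seen. Of 10 CDK inhibitor and D cyclin genes, 3 rose and 1 fell in the double knockout against wildtype, and neither this list nor those of DNA replication and mitosis passed with all libraries and no further term. With a term for the S number range, DNA replication (camera adjusted p = 0.0333) and mitosis (0.0353) passed upward, and so they did among S numbers 7 to 12 (0.0163 and 0.0138). With that term both also passed upward in the Scl knockout (0.00119 and 0.000101) and in the Lyl1 knockout (1.57e-05 and 2.29e-06). The mean mitosis level was 0.63, 0.51 and 0.26 in replicate 1 of the double, Scl and Lyl1 knockouts, on a log2 scale relative to wildtype. Replicates 2 and 3 of these genotypes were at -0.42 to -0.11, and wildtype 3 was at 0.49. The upward calls thus follow 1 library of each knockout. Ccnd3, a D cyclin gene, fell from 615 ± 46.2 to 349 ± 35.2 CPM (SD, n = 3 each), with a log2 change of -0.82 (SE 0.12). The inhibitor gene Cdkn2a rose from 0.513 ± 0.3 to 11.7 ± 11.6 CPM, Cdkn1a from 73.9 ± 49.3 to 265 ± 22.8 CPM, and Cdkn2c by 0.59 (edgeR adjusted p = 0.0354). The Cdkn2c call ended without double knockout 1 or 3 or wildtype 1 or 2 (0.0851 to 0.125) and with the 2 genotypes alone (0.104). Among S numbers 7 to 12, with 1 double knockout library, the calls of Cdkn1a and Cdkn2c ended, at log2 changes of 1.79 and 0.7. For the list the median was -0.27, the mean 0.32 and the camera direction up (adjusted p = 0.94), and the median was 0.14 under library totals. DNA replication genes had 3 of 30 up (E2f2, Rfc3, Lig1; 0 adjusted over the list alone; 6 under library totals; camera adjusted p = 0.445) and mitosis genes 1 of 32 up (Cenpa) and 1 down (Incenp; 0.939).

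Dense granule, stress and metabolic lists did not pass in that comparison either, apart from the mitochondrial and cholesterol lists in the alternatives named. Dense granule genes had 8 of 25 down and 3 up (Rab27a, Rab38, Slc18a2; median 0.02, mean -0.07, camera adjusted p = 0.598), but 15 up and 5 down under library totals (median 0.44). The p53 targets had Cdkn1a, Bax and Fas up and Mdm2 and Phlda3 down of 20 (0.569), and under library totals 9 were up and 2 down (median 0.55). Immediate early genes had Jun, Ier2, Btg2 and Klf2 up and Junb and Zfp36 down of 21 (0.821; median -0.02, mean -0.02, camera direction up, and median 0.39 with 7 up and 1 down under library totals). Mitochondrial transcripts had 2 of 7 up, mt-Nd4 and mt-Nd5, and 4 adjusted over the list alone (0.186), and 6 under library totals; the list passed upward with the S number term (0.0353) and among S numbers 7 to 12 (0.0244). Cholesterol synthesis genes had 9 of 21 down and Insig1 up (0.122), with a median of -0.38 that was 0.03 under library totals, where 7 were up and 2 down, and passed downward with limma voom (0.0278). Stress response genes of protein folding had Ddit4 up and Ddit3, Hspa5, Pdia6 and Dnajb9 down of 22 (0.257), with a median of -0.14 that was 0.28 under library totals, where 4 were up and 2 down.

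Olfr552 differed between libraries of 1 genotype. It was at 16.5, 18.2 and 15.5 CPM in wildtype, at 0.153 to 0.293 CPM in the Lyl1 knockout, at 0 to 0.238 CPM in the double knockout, and at 0.619, 0.0395 and 22.5 CPM in the Scl knockout. Col1a1 was at 2.62, 135 and 29.5 CPM in the 3 Scl knockout libraries.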
